A study of Arabidopsis thaliana with 4 samples.

How the data were processed

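Whole-plant RNA of Arabidopsis thaliana Col-0 was measured on 4 one-colour NimbleGen arrays, 1 of plants kept with acetonitrile and 3 of plants kept with (E)-2-hexenal for 30 min. Per the labels' protocols, plants were grown on peat pellets at 23 °C under 14 h of light and 10 h of dark. They were then closed in a 340 cm3 box in which 3 µL of 1 M hexenal in acetonitrile had been put on paper, at 25 °C and 80 µmol photons per square metre and second. Each RNA sample came from at least 6 plants. Per the labels' protocols, cDNA was made with an oligo-dT primer and labelled with Cy3 by random priming. The labels call the 3 hexenal samples biological replicates and give 1 control, so the spread between control samples is unknown.

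The authors deposited 1 linear intensity per locus and array, for 30361 loci. Background correction, normalization, the way probes were combined and detection calls are not given in the sources used here. No detection limit could be set, and low intensities may hold background, which makes fold changes from a dim control depend on it. The deposited intensities had lower quartiles that differed by 0.20 on the log2 scale between arrays, more than a tolerance of 0.1, so the log2 values were quantile normalized. The brightest loci lie near the top of the scale, where differences can be compressed. No scanner files were used here, and no genome build is named, so no coordinates are given. No count of reads lies behind the values, and the number of arrays limits the precision.

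Locus codes were matched to a RefSeq gene table of assembly TAIR10.1, used only for names. Of the 30361 loci 29976 matched and 10355 had a symbol, and the others are given by their code. No column of another sample was present. Probe sequences were not used here, so sharing of probes between near-identical genes was not tested.

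The hexenal arrays were compared with the control in R 4.3.3 with limma 3.58.1 (lmFit and eBayes without trend) and Benjamini-Hochberg adjustment over all loci. A gene was called at an adjusted p under 0.05 and at least a 2-fold change. The fit has 2 residual degrees of freedom per locus, all from the hexenal arrays. All p values are two-sided, except those of a one-sided hypergeometric test of gene families.

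Gene lists were tested with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 26 lists. The lists cover heat shock factors, small heat shock proteins, cytosolic and organelle chaperones, the unfolded protein response of the endoplasmic reticulum, DREB and CBF, ZAT, NAC, ethylene response and WRKY factors, glutathione transferases, electrophile detoxification, jasmonate biosynthesis and response, salicylate defence, redox genes, abscisate response, touch, calcium and MAP kinase genes, ethylene, phenylpropanoids, auxin and growth, photosynthesis, clock, reference genes, and markers of root and of flower or seed. They hold 376 loci. A locus was left out where the reference did not give it the list's name or a synonym. This removed 22 loci, 17 with no name in the reference and 5 with another name, and left 354. Of the 22 loci, 10 belonged to the small heat shock protein list, and 11 of the 22 were called. This rule was written beforehand, but a first run kept all 376 loci, and the rule was applied only after its results were seen. Keeping all 376 is now one of the alternatives.

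Genes are named by a rule. It takes the 10 largest rises and the 10 largest falls among called genes with all 3 hexenal arrays on one side of the control, up to 4 called members of each list by size of change, and HSFA2, DREB2A, HSP101, HSP90.1, MBF1C, ZAT10, ZAT12, RD29A, OPR1, CYP81D11, GSTU24, PDF1.2, LOX2, JAZ10, PR1, APX2, BIP3 and ACT2 whatever their result. Other members of a list may be given with their values where they did not pass. The groups, main tests, lists, naming rule and the first set of other settings were fixed before the data were examined. The rule that leaves loci out of the lists was written then too, but was first applied after results were seen.

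The settings tried in place of these were the values as deposited, median centring, cyclic loess, leaving out the dimmest 25% or 50% of loci, eBayes with trend and robust, treat against a log2 fold change of 0.5, no fold threshold, a 4-fold threshold, adding 16 before the log, and leaving out each hexenal replicate. For the lists they were camera with an estimated correlation, fry, and 10000 random lists matched on mean level. After the data were seen, eBayes with trend or robust alone, a block that pairs the control with hexenal replicate 3, the full lists, and an estimated correlation together with each replicate left out or with the block were added.

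The tests were checked on simulated data with 30361 loci, of which 200 were changed. Loci were drawn independently, with the control varying like the hexenal arrays and no effect shared within an array. The check therefore cannot show how the tests behave on lists of correlated genes or on arrays that pair up. The share recovered was 0% at a log2 change of 1, 6% at 2, 68% at 3 and 94% at 5, and 6 of 90 called loci were unchanged. For the lists, a simulated list of 20 loci changed by 1 had an adjusted p of 6.78e-16 with the preset correlation and 0.577 with an estimated one, and 0 of 50 unchanged lists were called by either. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.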

Results

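Gene expression was measured in whole plants of Arabidopsis thaliana Col-0, the common laboratory accession, 30 min after exposure to the vapour of (E)-2-hexenal, a reactive 6-carbon leaf aldehyde released by wounded leaves. The study asked which stress-related genes this volatile induces. Hexenal at 10 µM was measured on 3 arrays, labelled as biological replicates, and the acetonitrile solvent alone on 1 array. Each array gave 1 intensity for each of 30361 gene loci. The median deposited intensity was 941 on the control array and 982, 968 and 936 on hexenal arrays 1, 2 and 3. The number of arrays, with a single control, limits the precision of every value below. Fold changes are given as log2 differences between hexenal and control with their standard errors.

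After 30 min of hexenal, the genes called by the thresholds given below included heat shock factor and chaperone genes, and more of them rose (263) than fell (10). HSFA2, a heat-inducible transcription factor, rose from a log2 level of 8.07 to 14.46 ± 0.19 (SD, n = 3), or 83.6-fold. DREB2A, a regulator of drought and heat responses, rose 77.1-fold, and the co-chaperone gene BAG6 rose 44.9-fold. The small heat shock protein loci AT1G53540 and AT1G59860 had the highest measured fold changes of the called genes, 121-fold and 94.8-fold, from control levels in the dimmest 25% of loci. OFP16, an OVATE family gene, fell by 3.80 on the log2 scale, the largest fall among called genes.

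In all, 273 of 30361 loci (0.899%) passed an adjusted p threshold of 0.05 with at least a 2-fold change in limma's test with Benjamini-Hochberg adjustment, of which 263 were higher and 10 lower. The smallest adjusted p was 0.00608, and 2656 loci had an unadjusted p under 0.05 where 1518 would be so by chance. With hexenal array 1 in the control's place that number was higher, 2994, so the excess does not mark a hexenal effect, but no locus was then called. In that split the control lies among the 3 arrays, so any difference of it widens the residual spread and makes calls harder. All 273 called loci lay on the same side of the control in 3 of 3 hexenal arrays, so leaving out a replicate could not change their direction. The median rise of the called genes was 2.97, and 244 rose at least 4-fold. For 55 of the 263 higher genes the control level lay in the dimmest 25% of loci, where a fold change also depends on the background left in the values. The same holds for 8 of the 10 largest rises, all but HSFA2 and BAG6, so their sizes and order are uncertain. The residual spread comes from the 3 hexenal arrays alone, and the control is assumed to vary like them. Without hexenal replicate 2 it comes from replicates 1 and 3, which differed most of the hexenal pairs (median absolute difference 0.312). No locus was called without hexenal replicate 2, when 1546 had an unadjusted p under 0.05 and the smallest adjusted p was 0.104, although all 273 genes kept their direction and a 2-fold change.

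**Figure D1:**
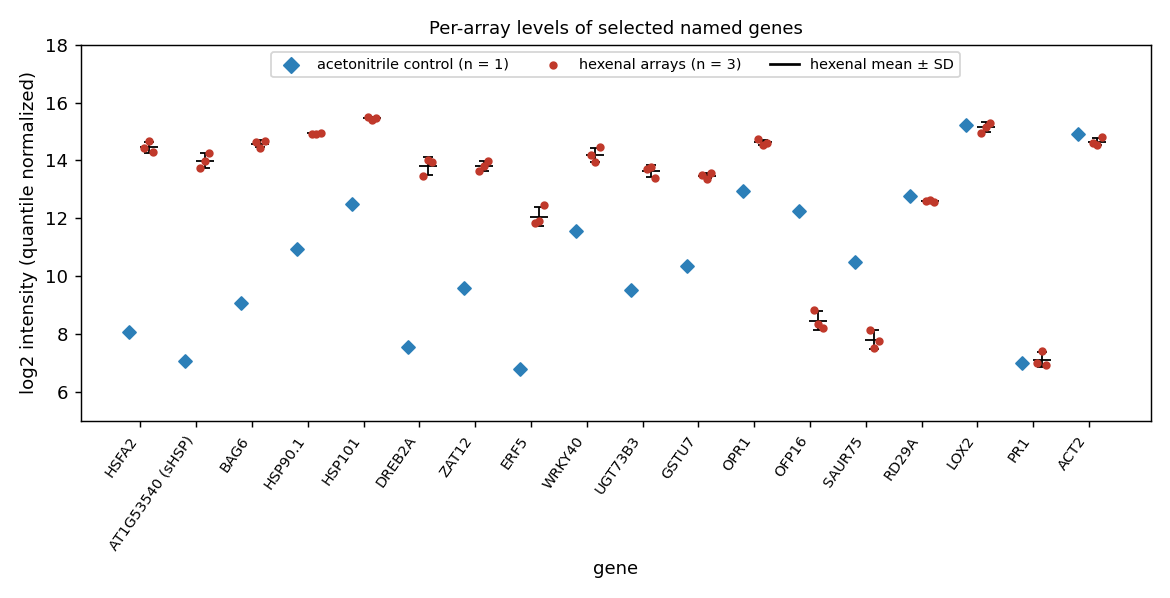
Levels of 18 selected genes on each array, as quantile-normalized log2 intensity. Diamonds are the control array, points the 3 hexenal arrays and bars their mean ± SD. HSFA2 lies at 8.07 on the control array and at a mean of 14.46 on the hexenal arrays, while OPR1, RD29A, LOX2, PR1 and ACT2 show no called difference.

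The other genes among the 10 largest rises were AT4G08555 (log2 fold change 6.25 ± 0.26 SE), AT1G05575 (6.20 ± 0.24), AT3G29000 (5.73 ± 0.25), the ubiquitin ligase gene CNI1 (5.73 ± 0.36) and the ethylene response factor gene ERF13 (5.44 ± 0.40). Among the 10 called falls were 3 loci of the SAUR family of early auxin-responsive genes. AT2G21210 (SAUR6) changed by -3.28 ± 0.41, SAUR75 by -2.67 ± 0.32 and AT4G38840 (SAUR14) by -2.64 ± 0.31. The remaining falls were those of AT5G57760 (-3.08 ± 0.32), the membrane-associated kinase regulator gene MAKR6 (-2.92 ± 0.37), AT3G61930 (-2.37 ± 0.27), the auxin-conjugate hydrolase homologue ILL5 (-2.26 ± 0.23), AT5G01740 (-2.25 ± 0.24) and AT1G49200 (-2.24 ± 0.28). AT2G21210, SAUR75, MAKR6 and AT1G49200 lost their calls without hexenal replicate 3 (adjusted p 0.0559 to 0.0593), and AT2G21210 also with 16 added before the log (0.0508). Near-identical copies, as in the small heat shock protein, SAUR, GSTU and UGT73 families, may share probes, so values of single members of these families are uncertain.

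Gene lists fixed in advance were tested next, to ask which pathways moved. Of 26 lists, 13 passed camera's test in limma with a preset correlation, all towards higher expression, and none passed with a correlation estimated for each list, where the smallest adjusted p was 0.0874 and 8 lists had an unadjusted p under 0.05. With the preset correlation camera sets the members of a list against the other loci. Its p values below therefore do not measure the spread between control samples, of which there is 1. Of the 354 list members, 55 were called.

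Genes of heat shock factors, small heat shock proteins and cytosolic chaperones rose, with the highest median of all 26 lists in the small heat shock proteins. Of 21 heat shock factor genes, 5 rose and none fell, and 9 rose when adjusted over the list alone. HSFA7A rose by 4.34 ± 0.25, HSFA7B (AT-HSFA7B) by 2.82 ± 0.26 and HSFA4A (HSF A4A) by 2.52 ± 0.24. The list's median log2 fold change was 0.84 (adjusted p = 1.59e-11 by camera in limma, and adjusted p = 0.0874 with an estimated correlation). Among 5 small heat shock protein genes, whose products bind unfolding proteins, HSP23.6-MITO rose by 5.19 ± 0.39 and HSP17.6II by 5.14 ± 0.29, and all 5 rose when adjusted over the list alone. The other members were at 4.46 ± 0.67 (ATHSP22.0), 4.19 ± 0.78 (HSP21) and 1.55 ± 0.27 (HSP17.4), not called over all loci. The 5 genes had a median of 4.46 (adjusted p = 7.07e-11, and adjusted p = 0.171 with an estimated correlation). The loci that the reference does not give the list's name were kept in a first run and left out after its results were seen. With them, 11 of 15 small heat shock protein genes rose. Adjusted over that list alone 14 rose and 1 fell, AT4G21870 at -2.37 ± 0.44, which was not called over all loci.

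Of 18 cytosolic chaperone and co-chaperone genes, 9 rose and none fell, and 10 rose when adjusted over the list alone. BAG6 rose by 5.49 ± 0.25, the peptidyl-prolyl isomerase gene ROF2 (AT5G48570) by 4.80 ± 0.29 and Fes1A, a co-chaperone of HSP70, by 4.42 ± 0.32. HSP90.1 rose by 3.99 ± 0.23, the heat-induced coactivator gene MBF1C by 3.09 ± 0.26 and HSP101, a protein disaggregase, by 2.97 ± 0.23. Over the 18 genes the median was 1.66 (adjusted p = 9.97e-20, and adjusted p = 0.0874 with an estimated correlation). In the single array pair formed by hexenal replicate 3 and the control, which lay closest to each other in the dim loci, the medians of the heat shock factor, small heat shock protein and cytosolic chaperone lists were 0.88, 5.40 and 1.53.

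The lists of organelle chaperones and of the endoplasmic reticulum's unfolded protein response did not pass the test. They hold no small heat shock protein genes, and HSP23.6-MITO, named for the mitochondrion, rose by 5.19 ± 0.39 in the list of those genes. Of 6 organelle chaperone genes only CLPB4, a mitochondrial disaggregase, rose (2.97 ± 0.27), and 2 did so when adjusted over the list alone. The list's median was -0.02 while its mean was 0.64, and camera in limma gave an adjusted p of 0.0799. Of 15 genes of the endoplasmic reticulum's unfolded protein response, ERDJ3A (ATERDJ3A) rose by 4.36 ± 0.35 and 14 were not called, with 2 higher when adjusted over the list alone. BIP3, a marker of that response, was at -0.22 ± 0.34. This list had a median of -0.07 and a mean of 0.44, with the test pointing to higher expression (adjusted p = 0.163).

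**Figure D2:**
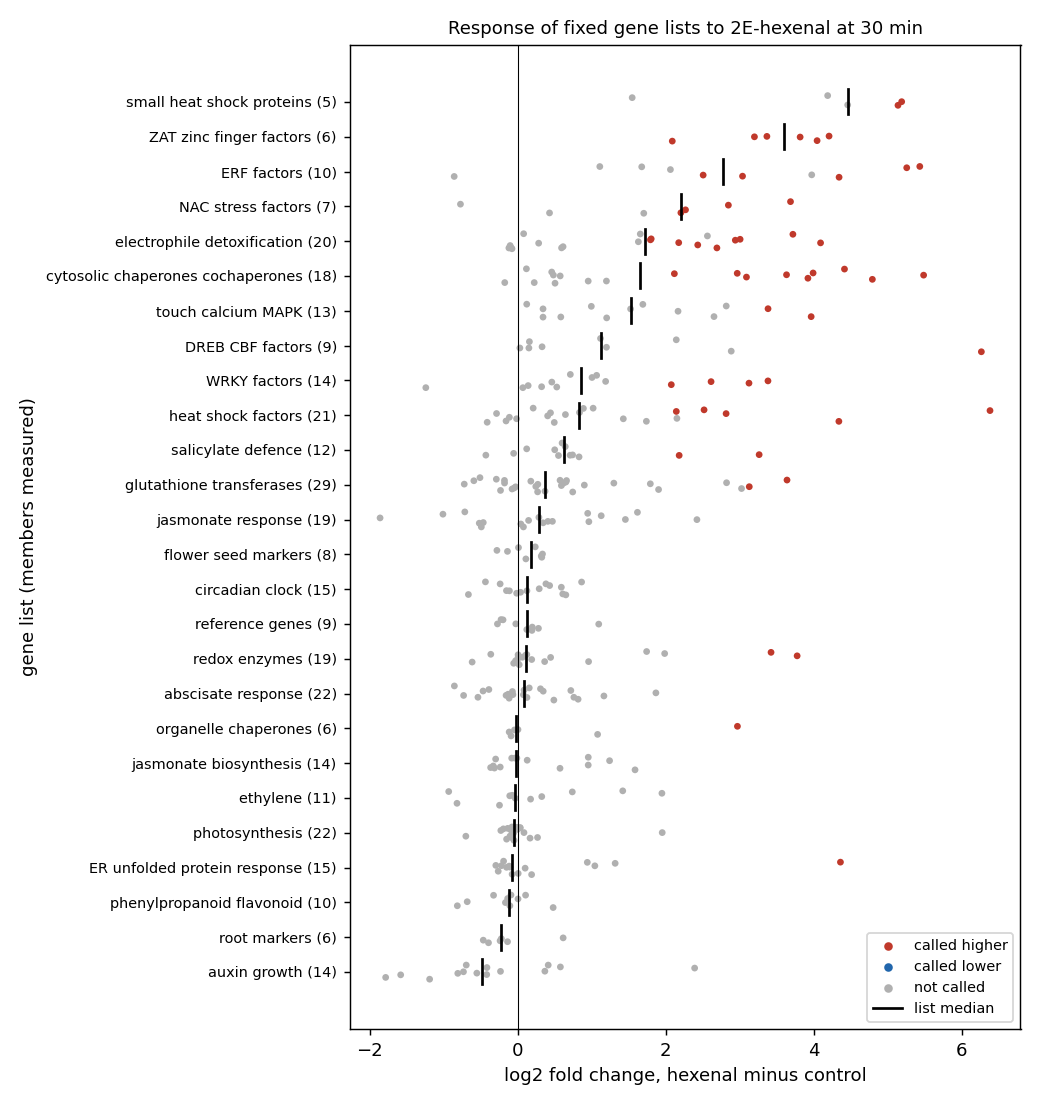
Log2 fold change (hexenal minus control) of each measured member of the 26 gene lists, 1 row of points per list, with the list median as a bar and called genes in colour. The small heat shock protein list has the highest median, 4.46, and the auxin and growth list the lowest, -0.48.

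Stress transcription factors rose in several families. All 6 ZAT zinc finger genes rose, among them ZAT12 (RHL41, 4.21 ± 0.26), ZAT6 (4.05 ± 0.23), ZAT11 (3.82 ± 0.32) and ZAT10 (STZ, 3.37 ± 0.24), and the same number rose when adjusted over the list alone (6). With the loci kept that the reference does not give the list's name, 6 of 8 rose. Of 10 ethylene response factor genes, 5 rose, including ERF5 (5.26 ± 0.33), ERF6 (4.35 ± 0.23) and ERF105 (AT5G51190, 3.04 ± 0.28), and 9 rose when adjusted over the list alone. Of 7 stress-related NAC genes, 4 rose in both counts, over all loci and adjusted over the list alone: NAC102 (3.69 ± 0.27), NAC032 (2.85 ± 0.31), ATAF2 (2.27 ± 0.27) and ATAF1 (2.21 ± 0.24). Of 14 WRKY genes, 4 rose, namely WRKY46 (3.38 ± 0.41), WRKY53 (3.13 ± 0.31), WRKY40 (2.62 ± 0.29) and WRKY33 (2.08 ± 0.25), the last not called without hexenal replicate 3 (adjusted p = 0.0509). Adjusted over the list alone, 7 WRKY genes rose and 1 fell. Of 9 DREB and CBF genes, DREB2A alone rose (6.27 ± 0.31), and 2 rose when adjusted over the list alone.

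The list medians were 3.59 for the ZAT genes, 2.77 for the ethylene response factors, 2.21 for the NAC genes, 0.86 for the WRKY genes and 1.12 for the DREB and CBF genes. Camera in limma with the preset correlation gave adjusted p values of 1.63e-15, 3.00e-15, 9.92e-07, 1.38e-07 and 9.27e-05 in that order. The adjusted p was 0.0874, 0.0874, 0.149, 0.187 and 0.317 with an estimated correlation. In hexenal replicate 3 against the control, the medians were 3.47, 2.50, 2.09, 1.17 and 0.39.

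Genes of electrophile detoxification rose as well. Of 20 such genes, 9 rose and none fell, and 12 rose when adjusted over the list alone. The glucosyltransferase genes UGT73B3 (17.1-fold), UGT73C1, UGT73B5 and UGT73B4 rose, the other members by 3.72 ± 0.40, 3.01 ± 0.26 and 2.94 ± 0.38 in that order, and UGT73B4 was not called with 16 added before the log (adjusted p = 0.0580). The cytochrome P450 gene CYP81D11 rose by 2.69 ± 0.28. OPR1, an oxophytodienoate reductase gene, was at 1.66 ± 0.24 and missed the threshold (adjusted p = 0.0647 by limma with Benjamini-Hochberg adjustment). Over the 20 genes the median was 1.73 (adjusted p = 2.44e-15 by camera, and adjusted p = 0.149 with an estimated correlation), and 1.70 in hexenal replicate 3 against the control.

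Of 29 glutathione transferase genes, whose enzymes conjugate reactive compounds to glutathione, GSTU1 (3.64 ± 0.39) and GSTU7 (3.13 ± 0.24) rose, and 6 rose when adjusted over the list alone. GSTU24 was at 3.03 ± 0.44 and was not called (adjusted p = 0.0670). Over the 29 genes the median was 0.37 (adjusted p = 9.27e-05, and adjusted p = 0.373 with an estimated correlation), and 0.29 in hexenal replicate 3 against the control. Of 19 redox genes, the protein kinase gene OXI1 (AGC2-1, 3.78 ± 0.30) and the membrane-associated cell death regulator gene BAP1 (3.43 ± 0.45) rose, neither of which encodes an antioxidant enzyme. The call of BAP1 was lost with median centring (adjusted p = 0.0517), cyclic loess (0.0570) and 16 added before the log (0.0595). Adjusted over the list alone, 4 redox genes rose. APX2, a heat-inducible ascorbate peroxidase gene, was at 1.99 ± 0.31 (adjusted p = 0.0784). The redox list's median was 0.11 (adjusted p = 0.00164, and adjusted p = 0.177 with an estimated correlation), and 0.18 in hexenal replicate 3 against the control.

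Among signalling genes, 2 of 13 touch, calcium and MAP kinase genes rose, the calmodulin-like CML37 (3.97 ± 0.29) and CML41 (3.39 ± 0.27), and 8 rose when adjusted over the list alone. That list's median was 1.53 (adjusted p = 8.53e-13, and adjusted p = 0.0874 with an estimated correlation). Of 12 salicylate and defence genes, the glutaredoxin gene GRX480 (3.27 ± 0.33) and the lipase-like immune regulator gene PAD4 (2.18 ± 0.25) rose, and the count was also 2 when adjusted over the list alone. The defence list's median was 0.62 (adjusted p = 5.01e-05, and adjusted p = 0.149 with an estimated correlation). In hexenal replicate 3 against the control the medians of these lists were 1.47 and 0.63. PR1, a late marker of salicylate signalling, was at 0.12 ± 0.29, and at -0.0016 with median centring.

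No gene of the jasmonate, abscisate, ethylene or phenylpropanoid lists was called by limma with Benjamini-Hochberg adjustment. Of 14 jasmonate biosynthesis genes 4 had an unadjusted p under 0.05, with a median of -0.02 and a mean of 0.27 (adjusted p = 0.198 by camera). LOX2, a chloroplast lipoxygenase gene, was at -0.08 ± 0.26, and at 0.010 without hexenal replicate 1. Of 19 jasmonate response genes 3 had an unadjusted p under 0.05, with a median of 0.29 (adjusted p = 0.0799). The repressor gene JAZ10 was at 1.13 ± 0.72 and the defensin gene PDF1.2 at -0.71 ± 0.45. Without hexenal replicate 3 the jasmonate response list had an adjusted p of 0.0066 with the preset correlation and 0.428 with an estimated one, and its adjusted p ran from 0.0066 to 0.783 over all alternatives. Of 22 abscisate response genes 4 had an unadjusted p under 0.05, with a median of 0.08 (adjusted p = 0.198), and RD29A (LTI78), a classical drought and cold marker, was at -0.15 ± 0.23. The 11 ethylene genes, 3 of them at an unadjusted p under 0.05, had a median of -0.03 and a mean of 0.22 (adjusted p = 0.656). The 10 phenylpropanoid and flavonoid genes, 1 of them at an unadjusted p under 0.05, had a median of -0.12 (adjusted p = 0.398). Adjusted over the list alone, 1 ethylene gene rose, and the count was 0 in the other lists of this paragraph.

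No list of growth, photosynthesis or reference genes passed the test either. Of 14 auxin and growth genes none was called over all loci and 4 had an unadjusted p under 0.05. Adjusted over the list alone 1 rose and 2 fell. The list's median was -0.48 (adjusted p = 0.0799 by camera in limma). Without hexenal replicate 1 it was 0.0025 with the preset correlation and 0.363 with an estimated one, and over all alternatives it ran from 0.0025 to 0.707. The 22 photosynthesis genes had a median of -0.05 and a mean of 0.02 (adjusted p = 0.899), the 15 clock genes a median of 0.13 (adjusted p = 0.198) and 9 reference genes a median of 0.13 (adjusted p = 0.490). In each of these lists 1 gene had an unadjusted p under 0.05 and the count adjusted over the list alone was 0. ACT2, an actin gene often used as a reference, was at -0.27 ± 0.25. The 6 root markers had a median of -0.23 (adjusted p = 0.471) and the 8 flower and seed markers a median of 0.18 (adjusted p = 0.616), with no member of either at an unadjusted p under 0.05 and 0 when adjusted over the list alone. The flower and seed markers had medians of 0.28, 0.093 and -0.037 in hexenal replicates 1, 2 and 3 against the control. Floral genes, singled out after their values were seen, were highest in replicate 1: in replicates 1, 2 and 3 against the control AP3 was at 1.17, -0.15 and -0.010, SEP3 at 0.95, 0.086 and -0.072, AG at 0.86, 0.10 and 0.027, AP1, which is not a list member, at 1.97, -0.067 and 0.043, and PI at 0.14, -0.26 and -0.29.

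The spread between arrays was then compared with the difference from the control. The median SD of a locus over the 3 hexenal arrays was 0.236, and the median absolute difference of the hexenal mean from the control was 0.265, so for a typical locus the difference did not stand clear of the spread. At least a 2-fold rise in each of the 3 hexenal arrays was seen for 772 loci, and at least a 2-fold fall for 156. With hexenal array 1 set against the remaining arrays instead, 338 loci were higher and 167 lower by that measure, with hexenal array 2 23 and 16, and with hexenal array 3 61 and 30. An exact permutation of 3 arrays against 1 cannot give a p under 0.25.

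**Figure D3:**
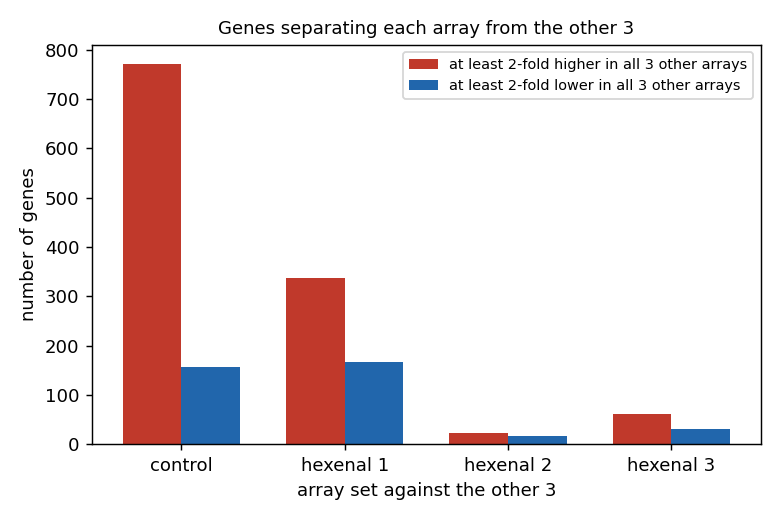
Number of loci at least 2-fold higher or lower in all 3 other arrays, with each of the 4 arrays in turn set against the rest. With the control as the single array, 772 loci were higher and 156 lower in the other arrays.

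The control resembled hexenal replicate 3 more than replicates 1 and 2. Across genes, which are not independent replicates, Pearson's r with the control was 0.974 for replicate 3, 0.961 for replicate 2 and 0.949 for replicate 1. Between hexenal arrays r was 0.984 for replicates 1 and 2, 0.982 for 2 and 3 and 0.971 for 1 and 3. Replicate 3 thus correlated more with replicate 2 than with the control. By the median absolute difference over all loci, however, replicate 3 lay nearer to the control (0.198) than to replicate 2 (0.272) or replicate 1 (0.312). In the dimmest 25% of loci the median absolute difference between control and replicate 3 was 0.0993, against 0.199 to 0.247 for the other pairs. With these array pairs as a block, a choice made after the data were seen, limma called 136 loci, 133 higher and 3 lower, of which 120 were among the 273. All 273 genes kept their direction and at least a 2-fold change with the block, and the 13 lists called with a preset correlation stayed called with it, while none was called with the block and an estimated correlation, where the smallest adjusted p was 0.372. OFP16 and AT5G57760 stayed called as lower, and the other 8 falls named above did not. Of the named rises 14 lost their call with the block, at adjusted p values of 0.0523 to 0.0939 by limma: HSFA7B (AT-HSFA7B), HSFA4A (HSF A4A), CLPB4, NAC032, ATAF1, ATAF2, ERF105 (AT5G51190), WRKY33, WRKY40, UGT73C1, UGT73B4, CYP81D11, GRX480 and PAD4.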

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

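The block that pairs the control with hexenal replicate 3, eBayes with trend alone and robust alone, the full lists, and an estimated correlation with a replicate left out or with the block were chosen after the data were seen. The deposited values, median centring, cyclic loess, the 4-fold threshold, no fold threshold and adding 16 gave 250 to 273 called genes against 273. All of the 273 that were tested kept their direction and at least a 2-fold change under every alternative. Settings that changed only the test, its threshold or the loci tested left the fold changes as they were, so both were fixed in advance there. With a replicate left out or with the block, the direction was fixed in advance, since all hexenal arrays lay on one side of the control. The effect with the block is replicate 3 minus the control alone. Leaving out the dimmest 50% of loci gave 480 called genes (448 higher, 32 lower), where fewer loci were tested, and leaving out the dimmest 25% gave 18 lower. eBayes with trend and robust gave 628 (573 and 55) and with trend alone 610 (554 and 56), while treat, which asks for more than a log2 of 0.5, gave 174 (170 and 4). With the block, which leaves 1 residual degree of freedom, 136 were called (133 and 3). Leaving out each hexenal replicate gave 0 to 388 called genes, 0 to 353 higher and 0 to 35 lower. Each of these fits has 1 residual degree of freedom. Without replicate 1 it called 388, without replicate 3 336 and without replicate 2 0, where 1546 loci had an unadjusted p under 0.05, and the cause of the 0 was not tested. No analysis paired by replicate number was possible because the control has 1 array, so the groups share fewer than 2 replicate numbers. Averaging over rows of a gene had no effect to test, since each locus has 1 row. For the lists, 0 were called with an estimated correlation, against 13, and 0 with it and any replicate left out or the block. The simulated changed list was missed with it too (adjusted p 0.577), but its loci were independent, so that miss decides nothing. The 13 called lists had estimated correlations of -0.152 (NAC) to 0.509, so gene correlation does not explain every lost call. Fry called 11, matched random lists 15, and the other list alternatives 13 or 14. Fry did not call the DREB and CBF, redox (both 0.0971) and glutathione transferase (0.123) lists and called the organelle chaperones (0.0116). Matched random lists did not call the redox list (0.197) and called the jasmonate response (0.0071), auxin and growth (0.0064) and flower and seed (0.0319) lists. The jasmonate response list was also called with median centring (0.0475) and without replicate 3 (0.0066; 0.428 with an estimated correlation), and the auxin list without the dimmest 25% (0.0274), without replicate 1 (0.0025; 0.363 with an estimated correlation) and with the block (0.0062). LOX2 lay at 0.091 with the block and from -0.16 to 0.010 with a replicate left out, and PR1 at -0.0016 with median centring, -0.063 with the block and from -0.022 to 0.22 with a replicate left out, none of them called. The median absolute difference from the control was 0.316 without the dimmest 25%, against 0.265. Of the named genes, BAP1 lost its call with median centring, cyclic loess and the added 16, AT2G21210 and UGT73B4 with the added 16, and AT2G21210, MAKR6, SAUR75, AT1G49200 and WRKY33 without replicate 3 (adjusted p 0.0509 to 0.0593). All called named genes lost it without replicate 2, and 8 falls and 14 rises with the block. OPR1, GSTU24 and APX2 gained theirs with trend and robust, GSTU24 also without replicate 1 or 3 and APX2 without replicate 1. The cause of these changes was not tested, also where fewer loci were tested. The lack of detection calls limits what can be said of dim loci.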

Other observations

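All tests in this part were chosen after the results were seen. Among 173 gene families of at least 10 loci, grouped by the stem of their reference symbol, rises were enriched in a few by a one-sided hypergeometric test (Fisher's exact test) against 9368 loci with such a symbol, of which 112 were called higher. Of 24 HSP loci 10 rose (adjusted p = 1.17e-11), of 58 UGT loci 9 (adjusted p = 2.04e-06), of 25 ERF loci 5 (adjusted p = 0.000565) and of 67 WRKY loci 6 (adjusted p = 0.00609). Of 79 NAC loci 5 rose (adjusted p = 0.0862). Members of these families share sequence, so their probes may not be independent, and a call in the HSP or UGT families does not count separate genes with certainty. With the array pairs as a block 133 of all loci were called higher, against 263.

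Genes outside the fixed lists that rose, picked after their values were seen, include the HSP70 gene HSP70T-2 (log2 fold change 5.08), the ethylene response factor gene ERF-1 (4.82), the glucosyltransferase gene DOGT1 (4.72), NAC004 (4.66) and the DREB-type repressor gene CEJ1 (4.37). The ubiquitin ligase genes PUB24 and PUB29 rose by 3.64 and 2.74. Chloroplast-encoded loci (67) had a median of -0.15 and mitochondrial ones (94) a median of -0.57, which was -1.05, -0.47 and -0.22 in hexenal replicates 1, 2 and 3 against the control. Of the 94 mitochondrial loci 80 were lower in all 3 hexenal arrays, and their median lay at percentile 0 of matched random lists, whose median was -0.028. The random lists were drawn locus by locus, so the percentile does not allow for loci that move together and does not measure the spread between samples. No locus of either organelle was called by limma, and 0 of either had an unadjusted p under 0.05.

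The first pattern is the called difference itself. With the control as the single array 273 genes were called by limma, and the highest count with a hexenal array in its place was 0, where 525 to 2994 loci had an unadjusted p under 0.05. Only 1 of the 4 splits gave as many, and 4 splits are too few for a share under 0.05. Differences between this control and the hexenal plants other than hexenal cannot be told apart from it with 1 control array.

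The next pattern is that hexenal replicate 3 lay closest to the control over all loci. Its median absolute difference from the control was 0.578 times the mean of those of replicates 1 and 2. A weaker exposure of replicate 3 stays open. It would give smaller rises there, and over the 24 of 44 heat-list genes that were on average at least 2-fold higher in replicates 1 and 2 the median ratio of the rise in replicate 3 to that in the others was 1.03 (95% bootstrap interval 0.961 to 1.07), and likewise 1.03 over the 10 of these below a log2 level of 13 on every hexenal array. Over 85 genes of the other lists chosen alike, however, the ratio was 0.922 (0.846 to 1.03), and 21 of them lay below 0.75. Choosing genes by their rise in replicates 1 and 2 by itself favours ratios below 1. Both intervals cover the spread over genes, not that between arrays. ERF2 was at 5.16, 4.04 and 2.74 and DDF1 at 3.02, 3.03 and 0.39 in replicates 1, 2 and 3 against the control, and RRTF1, which is not among the 354 list members, at 3.84, 3.64 and 1.29. Members of the same lists also went the other way, with CBF2 at 2.33, 2.91 and 3.42 and ERF5 at 5.03, 5.10 and 5.65, so single genes decide nothing here. Labelling or hybridisation conditions shared by the control and replicate 3 are a candidate explanation. In the dimmest 25% of loci the next closest pair differed 2.01 times as much as that pair did. Members of the jasmonate response list went both ways, so their median decides nothing here. In replicates 1, 2 and 3 against the control the repressor genes JAZ7 and JAZ8 were at 3.88, 3.07 and 0.32 and at 2.68, 2.40 and -0.22. The output genes THI2.1 and VSP1 were at -3.84, -1.19 and -0.54 and at -1.12, -0.20 and -0.14. Each of these genes differed least from the control in replicate 3. Other members did not, with CYP94C1 at 1.14, 0.11 and -2.80 and JAZ4 at 0.50, 0.21 and 0.70. A difference between lots of plants was not tested.

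The last pattern is a shift of the SAUR family, early auxin-responsive genes of growing tissue. Of 79 SAUR loci 3 were called lower and 0 higher by limma, 25 had an unadjusted p under 0.05, and 14 were at least 2-fold lower in all 3 hexenal arrays against 1 higher. All 3 calls are lost with the block (adjusted p 0.0955 to 0.112) and without replicate 2 (0.170 to 0.214), and those of AT2G21210 (0.0561) and SAUR75 (0.0559) without replicate 3 as well. The median was -0.20 (unadjusted camera p = 1.20e-05 with the preset correlation and p = 0.262 with an estimated correlation). Conditions shared by the control and replicate 3 would leave no shift between those arrays. The SAUR median of replicate 3 minus control, -0.24, lay at percentile 0 of matched lists, but it rests on a single array pair and is no further from 0 than the SAUR median moved with a hexenal array as the single one, so these conditions stay open. Variation between lots of plants may give such a shift too: with hexenal array 2 as the single array the SAUR median moved by 0.303, further than with the control, although at least 2-fold lower SAUR loci then numbered 0, as with hexenal array 3, and 1 with hexenal array 1, against the 14 with the control. An early loss of auxin-responsive transcripts under hexenal is a hypothesis that 1 control cannot settle.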
